A study of Homo sapiens with 4 samples.

How the data were processed

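H3K4bhb, the beta-hydroxybutyrylated form of lysine 4 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in HK-2 cells, an established human line of renal tubular epithelium. The 4 libraries formed 2 treatments, hydrogen peroxide (H2O2) alone and H2O2 after pretreatment with the sodium salt of beta-hydroxybutyrate (BHBNa). Each treatment had 1 immunoprecipitated (IP) library and 1 control library. The labels were contradictory on the control, which the titles called IgG and the library names called input. Per the labels' protocols, chromatin was fixed with formaldehyde and sonicated, and libraries were read as 150 bp pairs.

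Per the submitters' processing notes, the tools included fastp 0.20.1, Bowtie2 2.4.2, MACS2 2.2.7.1, ChIPseeker, HOMER and DiffBind, on the human build GRCh38. The role and settings of each were not given in the sources used here. The 2 files of a treatment, filed under its IP and its control library, were compared row by row. They held the same peaks: 100% of names, chromosomes, ends and scores were equal, and starts differed by 1 bp, the difference between counting from 0 and from 1. Each treatment therefore had 1 peak list, called from 1 IP library, and no separate control peaks entered the comparisons. For each peak the authors deposited a score, a ratio (the fold enrichment of the summit over background), the −log10 of its p-value and of its q-value, and a summit position. The score was the whole part of 10 times the −log10 p deposited by the authors in 100% of rows. The lowest −log10 p was 3.00 in both lists, so peaks had passed a p of about 0.001 and no limit on q.

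The number of IP fragments at each summit (pileup) and the local control background were recovered from the fold and the p, taking the fold as (pileup + 1) over (background + 1) and the p as the Poisson chance of more than the pileup. A whole-number pileup matched the deposited p within 0.001 on the −log10 scale, or a proportional tolerance for the highest values, for 100% of peaks in both lists. With the chance of at least the pileup instead, 0.6% of the fold and p pairs tried in the H2O2 list and 1% of those in the H2O2 + BHBNa list matched. On 1908 peaks simulated with known pileups, 99.9% were recovered. The lowest background in a list is its genome-wide level and scales with IP depth. It was 0.274 fragments in the H2O2 list and 0.102 in the H2O2 + BHBNa list. Assuming an effective genome of 2.7 Gb and fragments as long as the narrowest peak (232 and 245 bp), these levels correspond to 3.19 and 1.13 M IP fragments. The step between background values put the control libraries at 17.4 and 46.9 times the IP depth, or 55.7 and 52.8 M fragments. Of the peaks with low pileups, 42.2% and 30.5% fell on that step, where chance gives 1.05% and 2.81%. These depths are estimates from the peak lists, since read totals were not given in the sources used here.

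Genes came from the RefSeq table of GRCh38, the build of the files, as 19974 protein-coding genes on chromosomes 1 to 22 and X. The table used here had no strand, transcripts or sequence. The planned promoter window was therefore replaced by a gene end, within 1 kb of either annotated end of a gene, and the planned classes of UTR, exon and intron by gene body and intergenic. A gene end can be the start or the finish of transcription. A peak was called in or near a gene when its summit lay in the gene or within 1 kb of it. This wider assignment was chosen after seeing the data, because few genes had a peak at an end.

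Overlap was counted at 1 bp or more with bedtools 2.31.1. Expected values came from 100 sets of positions shuffled over the primary chromosomes, and from 100 sets shifted by 50 to 500 kb, the second chosen after seeing the data. For 26 gene lists fixed before the data were examined, the count of members with a peak was placed among 10000 random lists of the same size. Matching on promoter CpG content was not possible without sequence, so these lists were unmatched. Lists matched on gene length in 20 bins were added after seeing the data, as was the union of 10 mitochondrial and fuel lists. Intervals of shares are 95% Wilson intervals and cover counting error only. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and were tested on simulated data with planted overlaps, planted gene-end summits and planted list enrichments.

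Named genes followed a rule fixed before the data were examined. For each list described, it takes up to 2 members with the highest fold in the H2O2 + BHBNa list alone and up to 2 with a peak in both lists. Within a list it takes no member for a peak in the H2O2 list alone, so named members lean toward the H2O2 + BHBNa list. Over all genes it takes the 8 highest gene-end peaks in each list alone. It adds the 5 highest peaks of each list elsewhere on primary chromosomes, and members of the ketone body and biogenesis lists, among them PPARGC1A, TFAM, NRF1, BDH1, OXCT1, CPT1A and SLC16A1. Some genes that the rule takes are not reported here. The rule was applied to gene ends and, after seeing the data, to genes with a peak in or near them. Chromosome Y and unplaced contigs were left out of gene counts. Alternatives were stricter limits on q and fold, merged peaks, autosomes, other definitions of overlap, a 3 kb window, peaks touching the window with any part, and a longer list shortened to the length of the other. With 1 library per group, no difference between treatments has a replicate check, and no p-value between treatments was computed for peaks or genes. The only p-values computed here are for relations over chromosomes, among them that of the ratio of the lists' peak numbers. They do not measure spread between libraries.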

Results

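HK-2 cells exposed to H2O2, an oxidant, were compared with HK-2 cells given BHBNa before H2O2. The question was where H3K4bhb lies in the genome under each treatment, and whether genes of mitochondrial energy metabolism carry it. Each treatment gave 1 list of H3K4bhb peaks from 1 IP library, so the difference has no replicate check and every comparison describes these libraries. The genome-wide background recovered from the peaks, which scales with IP depth, was 2.68 times as high in the H2O2 list as in the H2O2 + BHBNa list.

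PPARGC1A, which encodes the coactivator PGC-1alpha of mitochondrial biogenesis, held 2 peaks in the H2O2 list and 6 in the H2O2 + BHBNa list. The gene spans 681 kb (chromosome 4, 23792021 to 24472905), for which the average peak density of each list gives 1.41 and 2.59 peaks. Chromosome 4 held more peaks per Mb than these averages, 3.10 and 4.22 against 2.06 and 3.79. The H2O2 + BHBNa peaks with summits at 24075568 and 24122600 rested on 2 IP fragments each. The H2O2 list held no peak with fewer than 3 fragments. No peak lay at an end of the gene. The highest PPARGC1A peak of the H2O2 + BHBNa list, at 24161675 to 24162005, had a fold enrichment of 4.46 and a q of 0.00473, from 4 IP fragments. In that list 2 of the 6 peaks had a q of at most 0.05, against 0 of 2 in the H2O2 list. The higher H2O2 peak had more fragments, 6, with a fold of 3.92 and a q of 0.187. Its background was 0.784, against 0.122 at the highest H2O2 + BHBNa peak, so the limit on q was reached with fewer fragments in the latter list. NRF1, a transcription factor of nuclear genes for mitochondrial proteins, held 0 peaks in the H2O2 list and 2 in the H2O2 + BHBNa list, the higher at a fold of 2.63 from 2 IP fragments. TFAM, BDH1, OXCT1, CPT1A and SLC16A1, which act in mitochondrial DNA maintenance, ketone body use, fatty acid import and monocarboxylate transport, had 0 peaks in or near them in both lists. For these shorter genes the average peak density gives at most 0.293 and 0.540 peaks, both for OXCT1, so 0 peaks tell little.

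**Figure D1:**
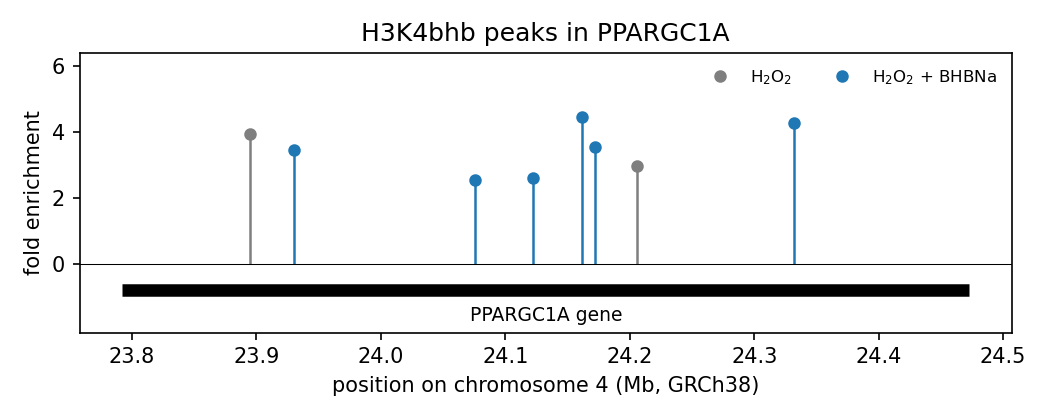
H3K4bhb peaks in PPARGC1A by position on chromosome 4 (Mb, x axis) and the authors' fold enrichment (y axis), with grey for H2O2, blue for H2O2 + BHBNa and the gene as a black bar. The 2 peaks of the H2O2 list and the 6 of the H2O2 + BHBNa list lie at different positions inside the gene.

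Genes of oxidative phosphorylation complex I had peaks in or near 4 of 41 members in the H2O2 list and 7 of 41 in the H2O2 + BHBNa list. Length-matched random lists gave means of 1.21 and 2.84 members, and the observed counts stood at percentiles 98.6 and 99.4. Complex I was the 1 list of 26 above the central 95% of length-matched lists in each peak list, where chance gives 0.65. Among unmatched lists it stood at percentiles 68.5 and 62.2. NDUFS4, a subunit, had a peak inside the gene in the H2O2 + BHBNa list alone, with a fold of 4.25 and a q of 0.0191. No complex I member had a peak with a q of at most 0.05 in the H2O2 list. NDUFAF2 and NDUFB5 had a peak in both lists, at different positions. The H2O2 + BHBNa peak in NDUFAF2 rested on 2 IP fragments. Peaks were found in or near 0 of 20 genes of complexes II and III and 0 of 21 of ATP synthase in both lists. Complex IV and cytochrome c had 0 and 1 of 26 members in the H2O2 and H2O2 + BHBNa lists, the latter being COX16. The COX16 peak rested on 2 IP fragments, and the H2O2 list held no peak with fewer than 3.

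Counts for the other mitochondrial and fuel lists are given for H2O2 first and H2O2 + BHBNa second. The TCA cycle and pyruvate entry had 2 and 4 of 35 members, with OGDHL in the H2O2 + BHBNa list alone and SUCLG2 in both. Fatty acid beta-oxidation had 2 and 3 of 39, with ACOX3 and ACADM in the H2O2 + BHBNa list alone. ACADL, a long-chain acyl-CoA dehydrogenase, had a gene-end peak in the H2O2 list alone, with a fold of 3.99 and a q of 0.18. Ketone body metabolism and monocarboxylate transport had 4 and 3 of 23. Of these members, 3 were in the H2O2 list alone, which the naming rule does not take. The acetyl-CoA synthetases ACSS1 and ACSS2 were in the H2O2 + BHBNa list alone. HMGCLL1, a lyase of ketone body synthesis, had peaks in both lists and a fold of 4.78 (q of 0.00658) in the H2O2 + BHBNa list. Mitochondrial biogenesis and dynamics had 2 and 6 of 33, where length-matched lists gave means of 2.98 and 5.89. OPA1 and SIRT3 were in the H2O2 + BHBNa list alone, and ESRRG and PPARGC1A in both. The peaks in OPA1 and SIRT3 had a q of 0.326. In SUCLG2, HMGCLL1, ESRRG and PPARGC1A, peaks of the H2O2 list overlapped none of the H2O2 + BHBNa list. The mitochondrial ribosome had 0 and 5 of 77, with MRPS28 and MRPL14 among the 5, and mitochondrial protein import had 0 and 2 of 35, TIMM17A and TIMM9. The peaks of OGDHL, ACSS1, ACSS2, SIRT3 and TIMM9 had a q of 0.326 and rested on 2 IP fragments. The H2O2 list held no peak with fewer than 3, so depth in part sets which list holds such peaks. Over these 10 lists together, 350 genes, 14 and 31 had a peak in or near them, where length-matched lists gave 13.8 and 31.7, at percentiles 54.7 and 45.2. At gene ends the counts were 1 (ACADL) and 2 (OGDHL among them) of 350. Of the 26 lists, 25 and 19 had 0 members with a gene-end peak, too few for percentiles at gene ends to tell lists apart.

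Among stress and kidney lists, glycolysis had 1 of 31 members with a peak in or near it in the H2O2 list. In the H2O2 + BHBNa list it had 6, and length-matched lists gave means of 1.29 and 3.35. PFKP had a fold of 2.72 from 2 IP fragments in the H2O2 + BHBNa list alone, and PGK1 had a gene-end peak there with a fold of 2.58. Proximal tubule identity and transport had 5 and 9 of 38, where length-matched lists gave means of 3.9 and 7.5. SLC13A3, a dicarboxylate transporter of the proximal tubule, had a peak at the same place in both lists (chromosome 20, 46655982 to 46656642 in the H2O2 list and 46656093 to 46656579 in the H2O2 + BHBNa list), with folds of 5.22 and 7.01. At the SLC13A3 peaks the control background was 2.06 and 0.426 fragments, above the genome-wide levels of 0.274 and 0.102. CUBN, the cubilin receptor, had peaks in both lists, and HNF4G and PAX8 in the H2O2 + BHBNa list alone. Lysine acylation and deacylation enzymes had 4 and 11 of 45, where length-matched lists gave means of 5.56 and 10.3. The demethylase KDM5C, at a fold of 4.44, and the acetyltransferase KAT6A, at 3.31, had a peak in the H2O2 + BHBNa list alone. HDAC9 and YEATS2 had peaks in both. KDM1A, a histone demethylase, had a gene-end peak in the H2O2 + BHBNa list with a fold of 2.65. Fibrosis and EMT had 5 and 6 of 32, with COL4A2 at a fold of 4.54 in the H2O2 + BHBNa list alone and COL4A1 and CDH2 in both. Apoptosis and ferroptosis had 1 and 5 of 29, with APAF1 and BIRC2 in the H2O2 + BHBNa list alone, BCL2 in both, and a gene-end peak at CASP8. The p53 and DNA damage response had 1 and 5 of 31, with ATR in the H2O2 + BHBNa list alone, ATM in both, and a gene-end peak at TIGAR. Mitophagy and autophagy had 3 and 7 of 44, with AMBRA1 in both, where length-matched lists gave means of 4.48 and 8.41. NRF2 targets and antioxidant enzymes had 3 and 3 of 50, with SOD2 in the H2O2 + BHBNa list alone and FOXO3 in both. Apart from SLC13A3, the genes named here with peaks in both lists held them at positions that did not overlap. The gene-end peaks at PGK1, KDM1A and CASP8 also rested on 2 IP fragments. So did the highest H2O2 + BHBNa peaks in PAX8, SOD2, ATM and BCL2. The H2O2 list held no peak with fewer than 3.

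Genes outside the studied cell type held peaks too. Genes of other tissues, a control list, had 1 and 3 of 51 members, where length-matched lists gave means of 1.0 and 1.89. The olfactory receptor OR1D2 had a gene-end peak in the H2O2 + BHBNa list. Markers of other cell types had 1 and 5 of 28, where length-matched lists gave means of 2.36 and 4.96. VWF and TEK had a peak in the H2O2 + BHBNa list alone. Markers of other nephron segments had 1 and 3 of 19, with SLC26A4 and CALB1 in the H2O2 + BHBNa list alone. Among the remaining lists, cytosolic ribosomal proteins had 2 and 3 of 75, and cell cycle and replication 2 and 3 of 38, with CDK6 and TOP2A in the H2O2 + BHBNa list alone. NF-kB and inflammatory response had 1 and 1 of 38, immediate-early and stress transcription factors 0 and 1 of 36, and tubular injury markers 0 and 1 of 21, the latter being TIMP2. The TIMP2 peak rested on 2 IP fragments. The H2O2 + BHBNa list had the higher count in 21 of the 26 lists, an equal count in 4 and a lower count in 1, ketone body metabolism. It also held 1.84 times as many peaks.

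**Figure D2:**
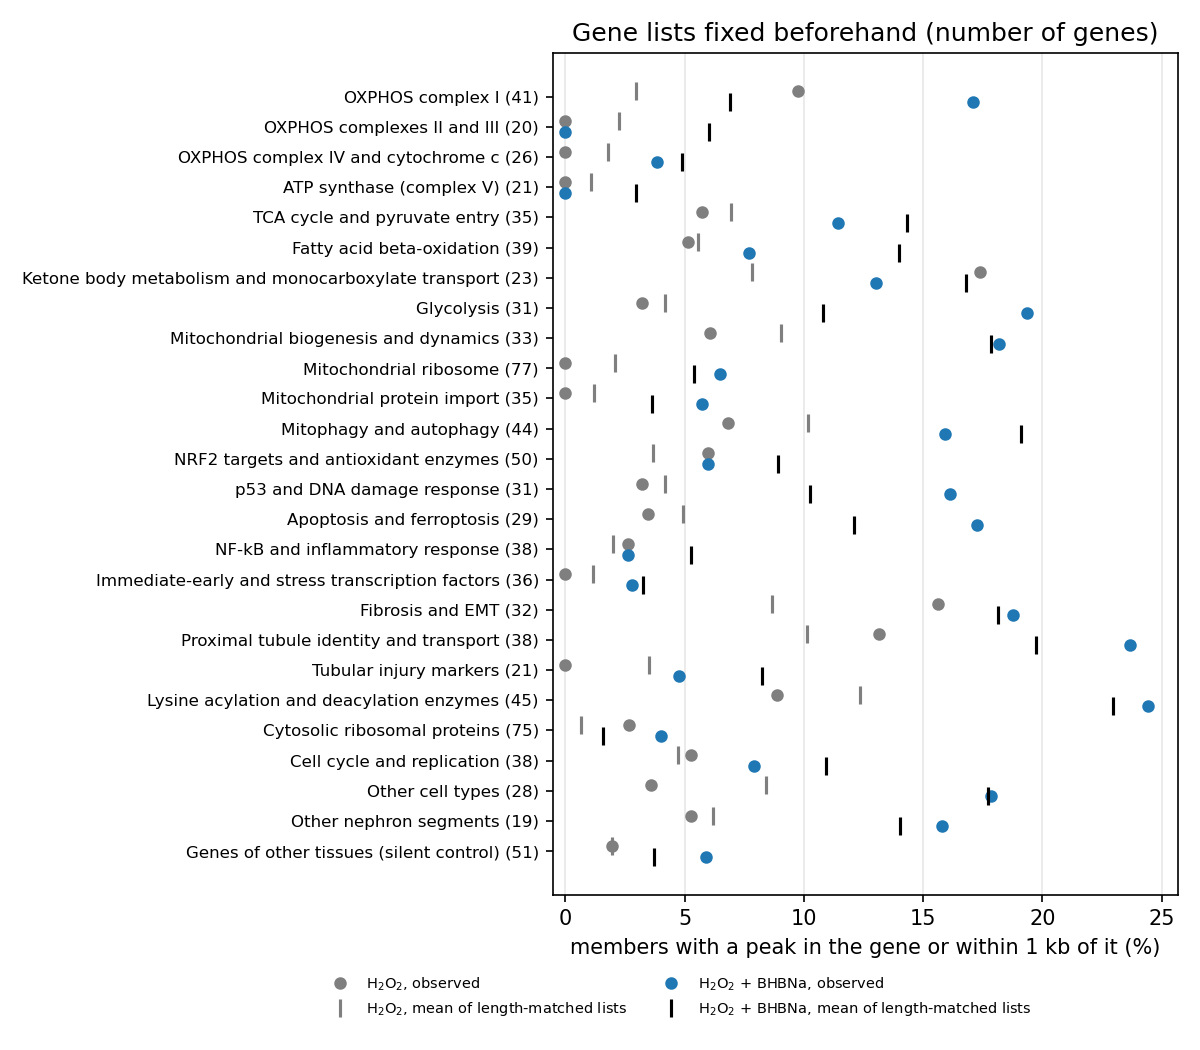
Share of members of each of 26 gene lists with a peak in or near the gene (%, x axis), with the number of genes in brackets, grey points for H2O2 and blue for H2O2 + BHBNa, and ticks for the mean of length-matched random lists. Complex I, with 4 and 7 of 41 members, lies to the right of both of its ticks by the most in percentile.

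Over all genes, the highest gene-end peaks of the H2O2 + BHBNa list alone were at ADAMTS15, DPRX, PDIA4, GFRA1, OR10J5, EFCAB13, LMO2 and NMT2. The peaks at ADAMTS15 (chromosome 11, 130447847 to 130448225), DPRX (chromosome 19, 53600140 to 53600484) and PDIA4, an endoplasmic reticulum disulfide isomerase (chromosome 7, 149028306 to 149028673), each had a fold of 5.44 and a q of 0.000148 from 5 IP fragments. The highest of the H2O2 list alone were at ACSM4, MYOZ2, OR13C8, CRKL, DIPK1A, ACADL, NDP and SLC7A3. ACSM4, a medium-chain acyl-CoA synthetase (peak on chromosome 12, 7328712 to 7329056), had a fold of 5.74 and a q of 0.000772 from 10 fragments. MYOZ2 (chromosome 4, 119187189 to 119187449) had a fold of 4.92 and a q of 0.0272. In total 50 genes had a gene-end peak in the H2O2 list and 161 in the H2O2 + BHBNa list, with 0 in both, where independent lists of that size share 0.403. At a q of at most 0.05 the counts were 2 and 31. Because no gene had a gene-end peak in both lists, folds at shared gene ends could not be set side by side. Within 3 kb, 8 genes had one in both, among them EZH2 and NSD2, histone methyltransferases named here after their values were seen. The median fold of the 8 was 3.25 in the H2O2 list (interquartile range 3.12 to 3.63) and 2.81 in the H2O2 + BHBNa list (2.72 to 4.05). In the latter 3 of the 8 folds were 2.72, the value of 2 fragments over the genome-wide background, so these medians are set by depth in part and do not compare enrichment.

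Gene ends held 48 of 6232 summits on primary chromosomes in the H2O2 list, 0.77% (0.581 to 1.02), and 147 of 11464 in the H2O2 + BHBNa list, 1.28% (1.09 to 1.51). Positions shifted by 50 to 500 kb gave 1.56% (range 1.06 to 2.04) and 2.16% (1.88 to 2.55), so both lists had fewer summits at gene ends than any of 100 shifted sets. Summits with a q of at most 0.05 lay at gene ends in 0.452% and 1.74% of cases, within the ranges of their shifted sets (0.226 to 3.62 and 1.51 to 3.08). Shuffled positions gave 2.41% and 2.38%. Gene bodies held 37.2% and 41.1% of summits, and intergenic sequence 62% and 57.6%. Genes with a peak in or near them numbered 1597 and 3087, with 868 in both, where 791 would be shared by chance within 50 bins of gene length. Their median lengths were 177 and 123 kb, against 24.2 kb over all genes.

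**Figure D3:**
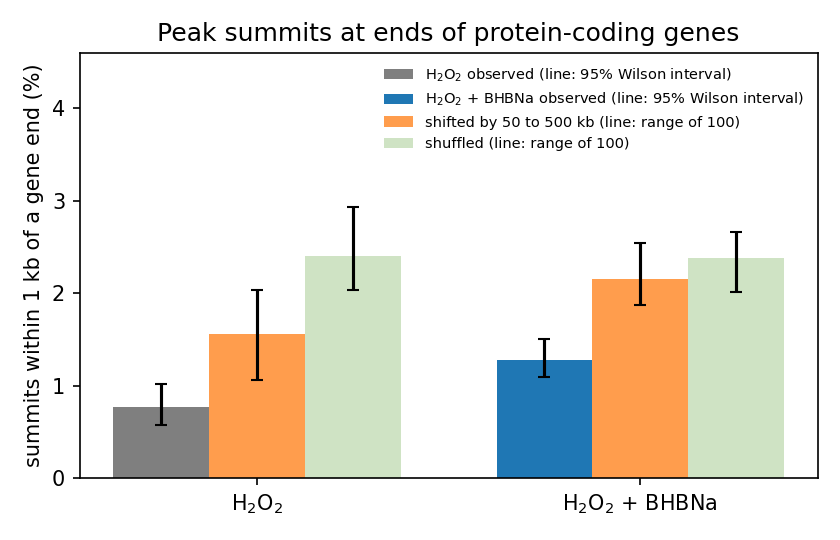
Summits within 1 kb of an end of a protein-coding gene (%, y axis) in each list, with 95% Wilson intervals, beside the mean and range of 100 shifted and 100 shuffled sets of positions. The observed shares, 0.77% and 1.28%, lie below the lowest shifted sets, 1.06% and 1.88%.

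The H2O2 list held 6251 peaks and the H2O2 + BHBNa list 11510. Median widths were 297 bp (interquartile range 259 to 355) and 324 bp (277 to 386), and the peaks covered 2004 and 3951 kb. The authors' fold enrichment, a value within each list, had medians of 3.51 and 2.72. A q of at most 0.05 was reached by 452 peaks of the H2O2 list, 7.23% (6.61 to 7.9), and by 1748 of the H2O2 + BHBNa list, 15.2% (14.5 to 15.9). The median peak rested on 4 IP fragments at its summit in the H2O2 list and on 2 in the H2O2 + BHBNa list, where 5970 peaks (51.9%) had exactly 2. With at least 3 fragments required of both, the lists held 6251 and 5540 peaks, a limit that removed peaks of the H2O2 + BHBNa list alone.

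**Figure D4:**
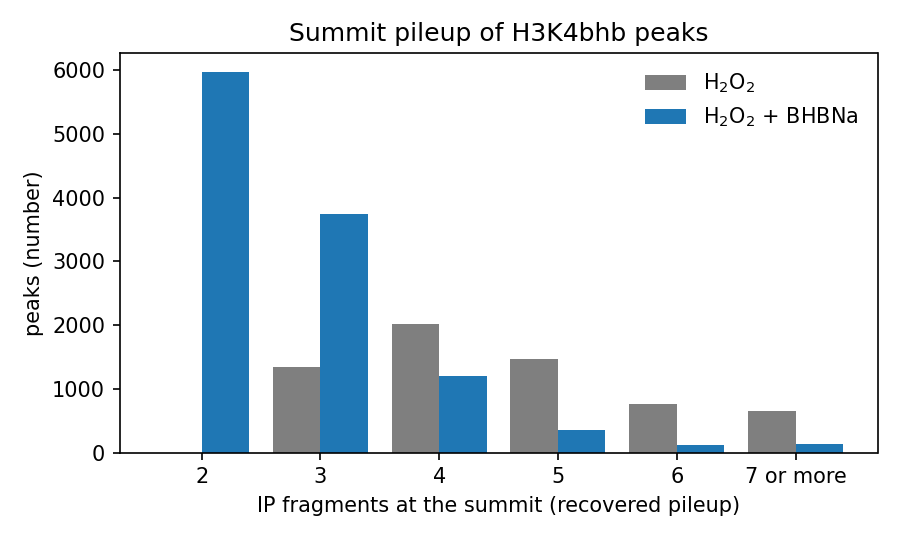
Number of peaks (y axis) by IP fragments recovered at the summit (x axis), with grey bars for H2O2 and blue for H2O2 + BHBNa. The blue bar at 2 fragments stands for 5970 of 11510 peaks, and the H2O2 list has none below 3.

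The lists shared 85 peaks, 1.36% of the H2O2 list (1.1 to 1.68) and 0.738% of the H2O2 + BHBNa list (0.598 to 0.912). Of these, 74 lay on primary chromosomes, where shifted positions gave a mean of 18.7 (8 to 31). Strong peaks were shared more often: 12 of 23 H2O2 peaks and 18 of 70 H2O2 + BHBNa peaks with a −log10 q of at least 5 were in the other list. On primary chromosomes, 15 shared pairs had a q of at most 0.05 in both lists, and 3 of them lay inside genes, SLC13A3 and, named after their values were seen, CNTNAP2 and SKAP1. On primary chromosomes, the highest fold outside gene ends in the H2O2 list was 11.9 at chromosome 12, 33995883 to 33996235, an intergenic peak 26.3 kb from ALG10 that the H2O2 + BHBNa list also held, at a fold of 5.22. The next were intergenic on chromosome 4, at 49709089 to 49711946 and 51107152 to 51107564, close to the centromere and in both lists. Those inside ACTR3C (chromosome 7, 150244093 to 150244522) and CADPS2 (chromosome 7, 122774227 to 122774508) had folds of 7.85 and 7.79 and were in the H2O2 list alone. In the H2O2 + BHBNa list the highest such folds on primary chromosomes were 18.5 at chromosome 1, 143253833 to 143254676, and 14.8 at chromosome 20, 28494720 to 28495934. Both were intergenic, 648 and 2318 kb from the nearest protein-coding gene, and in both lists. Intergenic peaks at chromosome 2, 194754172 to 194754466, and chromosome 1, 199950442 to 199950918, had folds of 10.3 and 9.96 in the H2O2 + BHBNa list alone. The chromosome 4 peak at 51107219 to 51107556 followed, at 9.74.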

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

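All tests in this part were chosen after the result was seen. Peaks also appeared on unplaced contigs and patches, sequences outside the chromosomes that the comparisons use, with 18 in the H2O2 list and 45 in the H2O2 + BHBNa list. Of the 10 peaks with the lowest q, 6 lay on such sequences in each list, and 10 of 10 were in both lists. Chance overlap is argued against as the source of shared peaks, since 74 were shared on primary chromosomes and the highest of 100 shifted sets gave 31. For the 10 H2O2 peaks with the lowest q a candidate explanation is repeat copies that are many in the cells and few in the reference: the control background there was at least 51.0 times the genome-wide level. In the H2O2 + BHBNa list it was over 10 times that level at 7 of the 10, but 2.09 to 5.43 times at the other 3, which hold the 2 highest folds of that list, 18.5 and 14.8, so that for these 3 the explanation stays open. H3K4bhb on satellite repeats stays open, because IP fragments exceeded that background there and no second antibody was analysed here.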

How the results depend on the processing

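Limits on q of at most 0.05 and on pileup, and length matching, were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and leaving out a replicate was likewise impossible. Values below give H2O2 first and H2O2 + BHBNa second. At a −log10 q of at least 5 there were 23 and 70 peaks (ratio 3.04), 10 shared, with 0% and 0% of summits at gene ends and 0 and 0 genes with a peak at an end. At 10 or more there were 12 and 18 peaks, 10 shared, and at a fold of at least 5 there were 177 and 297. At a q of at most 0.05 there were 452 and 1748 peaks (ratio 3.87), 23 shared, with 0.452% and 1.74% of summits at gene ends, 2 and 31 genes with a peak at an end, and 0 and 1 mitochondrial and fuel genes. These smaller counts follow from stricter limits. With a pileup of at least 3 the ratio of peak numbers reversed to 0.886, a limit that the H2O2 list meets throughout and that is stricter where the background is lower, with 5540 H2O2 + BHBNa peaks, 73 genes and 1 mitochondrial and fuel gene; at 4 it was 0.366, with 1796. Reciprocal 50% overlap left 52 shared peaks. A 3 kb window, wider by construction, gave 3.24% and 4.44% of summits, 216 and 566 genes, 8 in both, and 5 and 11 mitochondrial and fuel genes. With the longer list shortened, 1.66% of H2O2 + BHBNa summits lay at gene ends and 1 mitochondrial and fuel gene had a peak there; the cause was not tested. Peaks touching the window with any part gave 2 genes in both lists. Merging peaks and autosomes alone moved no peak number by over 1.5 times. In all, 27 of the main values' alternatives stayed close, 38 moved and 2 reversed. The percentile of mitochondrial and fuel genes with a peak in or near them went from 0.1 and 0 among unmatched lists to 54.7 and 45.2 among length-matched ones. Unmatched lists as an alternative to CpG-matched ones, and the nearest peak in place of the highest, were not run. At pileups of 2 to 4, depth limits which single genes can be told from chance.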

Other observations

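All tests in this part were chosen after the result was seen. Peak numbers of the lists differed more on gene-dense chromosomes. Chromosome 19 held 26 peaks in the H2O2 list and 116 in the H2O2 + BHBNa list, 4.46 times as many, and chromosome 22 held 26 and 98, whereas chromosome 4, poor in genes, held 589 and 803, 1.36 times as many. Over 23 chromosomes, which are not independent samples, the log2 ratio of peak numbers went with genes per Mb (Pearson r = 0.80, permutation p = 7e-05; Spearman rho = 0.73, permutation p = 0.0001). Adjusted over the 3 relations computed, these p were 0.0001 and 0.0002, and without chromosomes 19 and 17 r was 0.69. Among 350 mitochondrial and fuel genes, 2 in the H2O2 list and 6 in the H2O2 + BHBNa list had a peak in or near them at a q of at most 0.05. Over all 19974 genes the numbers were 153 and 632, a larger share in each list. These shares were not matched on gene length, and the 350 genes were shorter, with a median of 15.0 kb against 24.2 kb. They therefore do not tell whether mitochondrial and fuel genes carry fewer such peaks. The members included ACSL4 and ESRRG in the H2O2 list and ACOX3, HMGCLL1, NDUFS4, NDUFS6 and PPARGC1A in the H2O2 + BHBNa list. ACSL4 and NDUFS6 were named after their values were seen.

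For the H2O2 + BHBNa list holding 1.84 times as many peaks, a candidate explanation is depth: fragments placed at random at the recovered depths, with gaps of up to 150 bp joined, gave 2122 and 8073 peaks, a ratio of 3.80, equal to 33.9% and 70.1% of the lists. With gaps of up to 50 bp joined they gave 1393 and 6097, a ratio of 4.38, equal to 22.3% and 53% of the lists. Requiring a summit pileup of at least 3, which gave a ratio of 0.886, could remove peaks of the H2O2 + BHBNa list alone and so decides nothing. Peaks with a q of at most 0.05 were 3.87 times as many in the H2O2 + BHBNa list, but the limit was reached there with fewer fragments. A gain of H3K4bhb under BHBNa stays open and was not tested, since each treatment had 1 library.

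Few peaks lay at gene ends, which include the gene starts where H3K4 marks of active genes are usually found. Over all peaks the gene-end share was at most 0.594 times that of shifted positions, although with a q of at most 0.05 it lay within their range. In the full H2O2 and H2O2 + BHBNa lists, 0.77% and 1.28% of summits lay at gene ends. The lowest shifted sets gave 1.06% and 1.88%. For the full lists these values argue against peaks gathering at gene starts, since starts are among these ends. A gene end can be the start or the finish of transcription. An excess at starts offset by a lack at finishes was therefore not tested. Low recovery of GC-rich DNA could give the same picture and cannot be told apart from a mark that lies away from genes, because no sequence was analysed here. Peaks per Mb fell with genes per Mb in the H2O2 list (Pearson r = -0.73, permutation p = 5e-05; Spearman rho = -0.78, permutation p = 3e-05; adjusted 0.0001 and 9e-05), and r was -0.65 without chromosomes 19 and 17. In the H2O2 + BHBNa list r was -0.61 (permutation p = 0.00223; rho = -0.45, permutation p = 0.0324, both unmoved by adjustment) and -0.32 without these chromosomes, on which that relation rests.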
